A study of Homo sapiens with 6 samples.

How the data were processed

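MicroRNAs (miRNAs) were measured in 3 human colorectal cancer cell lines, Lovo, SW620 and HT29. Each line had been stably transfected with a vector carrying either a short hairpin RNA (shRNA) against TGFB1, the gene for the secreted growth factor TGF-β1, or a control shRNA. There was 1 array per line and shRNA, 6 arrays in all. Per the labels, total RNA was extracted with TRIzol and a column kit, labelled at its 3' end with the dye Hy3 and hybridised to 1-colour arrays with locked nucleic acid capture probes. The scanner and image software are not given in the sources used here.

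Groups were taken from the sample titles, which match the source names and the stated design. Another label field contradicts them: it gives the knockdown vector for both Lovo samples and the control vector for both HT29 samples, so that all labels point the same way only for the SW620 pair. TGFB1 is a messenger RNA and has no probe on a miRNA array, so the knockdown itself could not be checked. Per the labels the cultures were grown and harvested independently.

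The deposited raw table holds, per the file headers, the foreground intensity and the foreground minus background intensity of 15840 spots on each array. How the background was measured is not given in the sources used here. Of 3533 probe identifiers, 1891 named human miRNAs, 146 viral miRNAs and 23 other small RNAs, and 1402 carried no name. Nearly all human probes (1890) had 4 spots. The authors' value table holds a ratio: the median over a probe's spots of foreground minus background divided by 1 factor per array. This relation held within 1% for 100% of the values on each array, and cells were empty where the median was not above 0. The values are on a linear scale and not centred per probe. Column medians were 0.372 and 0.493 for Lovo knockdown and control, 0.551 and 0.446 for SW620, and 0.537 and 0.638 for HT29. The factor lay between 282.75 and 353.75, and how it was derived stays unknown.

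Spot intensities were background-corrected by normexp with an offset of 50, put on the log2 scale, averaged over replicate spots and quantile-normalised between the 6 arrays with limma 3.58.1 in R 4.3.3. A probe counted as detected on an array where the median over its spots of foreground minus background was at least 50. Human probes detected on at least 2 of 6 arrays were tested, which left 570; 256 were detected on all 6. Because intensities carry no counts, the number of arrays limits the precision. The median SD between replicate spots of a probe was 0.19 to 0.32 on the log2 scale.

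Knockdown was compared with control across lines by limma (lmFit, then eBayes with a trend) with the cell line as a block, since both arrays of a pair come from the same line, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The fit leaves 2 residual degrees of freedom. With 1 array per condition there is no test within a line, and there miRNAs detected on both arrays were counted by a difference of at least 2-fold, with the SE over replicate spots as technical error only. Cell lines were compared in the same way with the shRNA as a block. The 16 lists of miRNAs had 178 entries and 162 distinct members, so some miRNAs stand in more than 1 list. Of these lists, 14 had at least 3 tested members and were tested by limma's camera with a preset correlation of 0.01, with an estimated correlation, and by fry. Within a line, the median of a list was ranked among 10000 random lists matched on mean level. A probe not detected in a whole group has only a bound there, computed against the higher of the array's lowest detected signal and its own; list medians at bounds use the same values.

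Tests, lists, alternatives and the rule for named miRNAs were fixed before the data were examined. Across lines the rule took, among probes detected on all 6 arrays with the same sign in all 3 lines, the 12 highest and 12 lowest mean differences, and up to 5 probes each way detected on all arrays of one group and none of the other. Per line it took the 8 highest and 8 lowest among probes detected on both arrays. Between lines it took the 5 highest past the threshold, and list members could be named as examples. Any miRNA named outside this rule was chosen after its values were seen. Alternatives covered background correction, normalisation, the filter, averaging of spots, the value table, the variance model, the block and leaving out pairs or arrays. Scaling on spike control probes, robust eBayes, and fits without the probes of lowest variance were added after seeing the data. Spike control scaling aligned the arrays on each array's median over the spike control probes detected on all 6 arrays.

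The fits were tested on simulated data: 20 simulated data sets of the across-line comparison on 570 probes with independent noise. With 60 probes changed, 43.8% of those with a log2 difference of 1, 98.2% of those with 2 and 100% of those with 3 were called, and 6.11% of calls were false. With nothing changed, 4 of the 20 data sets still gave a call, and 3 of 20 gave a called list with the preset correlation. When the let-7 list was lowered by a log2 difference of 1, the preset correlation called it in 100% of the data sets, fry in 25% and the estimated correlation in 0%. The simulated noise was independent between probes, so these shares do not hold for lists whose members vary together. It was drawn with the variances that eBayes gave for the real data, so no simulated probe had zero variance. Each change was the same in all 3 lines, and the simulated arrays were not normalised again. The shares therefore do not carry over to the real data, where a mean log2 difference of 2.37 (miR-4711-3p) was not called. Figures were drawn with matplotlib 3.10.9.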

Results

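The arrays held 1 knockdown and 1 control sample from each of Lovo, SW620 and HT29, colorectal cancer lines grown in culture. Of the 1891 human miRNA probes, 542 and 481 were detected on the Lovo knockdown and control arrays, 398 and 502 on those of SW620, and 419 and 425 on those of HT29. The probe for miR-5100 was the brightest and held 11.2% to 14.5% of the summed human signal on each array. Median background was lowest on the Lovo knockdown array (86) and 138 to 202 on the others. Group labels follow the sample titles; for the Lovo control and the HT29 knockdown sample another label field names the opposite vector, so directions in those lines rest on the titles.

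The central question of the design is which miRNAs differ when TGFB1 is knocked down. Among miRNAs detected on all 6 arrays with 1 sign in every line, the lowest mean log2 differences belonged to miR-125b-5p (-2.01 ± 0.61, limma SE, n = 3 pairs), miR-140-3p (-1.75 ± 0.36), miR-193a-3p (-1.68 ± 0.40) and miR-199a-5p (-1.60 ± 0.40), a miRNA abundant in mesenchymal cells. The most even of these was miR-140-3p, at -1.96 in Lovo, -1.52 in SW620 and -1.77 in HT29, whereas miR-125b-5p ranged from -3.89 in Lovo to -0.08 in SW620, and its mean was -1.07 without the Lovo pair. The highest in the same set belonged to miR-4711-3p (2.37 ± 0.82), miR-4787-5p (1.26 ± 0.25) and miR-485-3p (1.20 ± 0.43); the mean of miR-4711-3p was 0.91 without the SW620 pair. Outside that set, members of the fixed lists that some arrays did not detect reached mean differences of similar size, at -1.76 ± 0.54 for let-7c, -1.72 ± 0.29 for miR-30a-5p and -1.61 ± 0.39 for miR-195-5p, detected on 5, 4 and 4 of the 6 arrays, with the undetected arrays entering near background. Of these, let-7c ranged from -3.11 in Lovo to -0.28 in HT29. The mean of miR-141-3p, 1.46 ± 0.69, rested on Lovo (4.02), whose arrays alone detected it, and was 0.18 without the Lovo pair. No single miRNA passed the limma test: 0 of 570 had an adjusted p under 0.05, the smallest being 0.154, and 61 had an unadjusted p under 0.05, 11 higher and 50 lower in knockdown (3 and 64 without normalisation between arrays). With arrays scaled on spike control probes, a setting added after seeing the data, 1 miRNA had an unadjusted p under 0.05, higher in knockdown, and limma's smallest adjusted p was 0.930.

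With the log2 differences held as they were, the count of 0 changed with the variance estimate. Quantile normalisation gave miR-5100 the same value on all 6 arrays, hence zero variance, and the fit's prior degrees of freedom were 6.45 with that probe and 10.02 without it. Without that probe limma called 2 miRNAs and with robust eBayes 6. Cyclic loess normalisation gave 5 calls and median scaling 32, of which 30 were lower; both move the differences as well as the variances, and these were not separated. It called 25 without the SW620 pair, 25 without the HT29 pair and 0 without the Lovo pair. Of 22 settings, 7 called miR-130a-3p and 7 called miR-30a-5p, while miR-140-3p and miR-193a-3p were each called in 6.

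**Figure D1:**
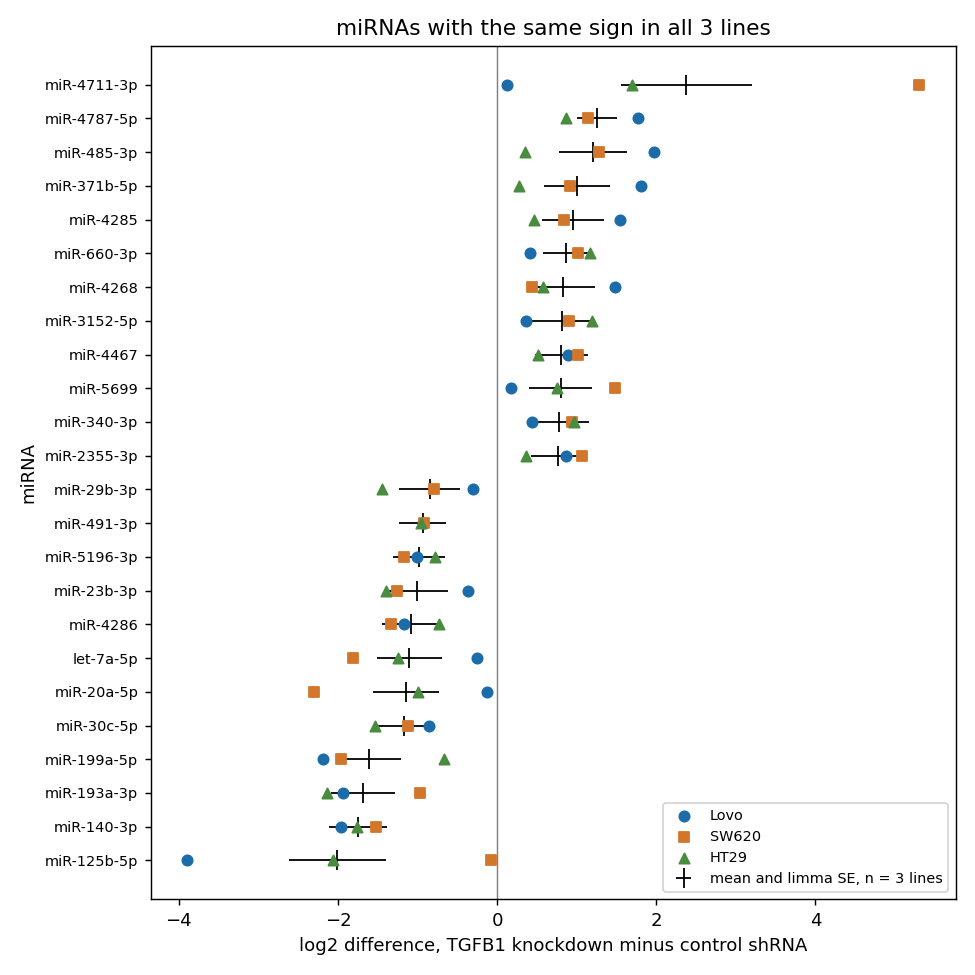
Log2 difference (knockdown minus control, x axis) of the 24 miRNAs with the highest and lowest means among those detected on all 6 arrays with 1 sign in all lines (y axis). Symbols are the 3 lines, bars the mean with its limma SE; the SW620 value of miR-4711-3p (5.30) and the Lovo value of miR-125b-5p (-3.89) lie far from the other lines.

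By the same rule, further miRNAs lower in every line were miR-30c-5p (-1.17 ± 0.37), miR-20a-5p (-1.14 ± 0.42), let-7a-5p (-1.10 ± 0.41), miR-4286 (-1.08 ± 0.36), miR-23b-3p (-1.01 ± 0.39), miR-5196-3p (-0.98 ± 0.33), miR-491-3p (-0.94 ± 0.29) and miR-29b-3p (-0.85 ± 0.38). Those higher in every line were miR-371b-5p (1.00 ± 0.41), miR-4285 (0.95 ± 0.39), miR-660-3p (0.87 ± 0.29), miR-4268 (0.83 ± 0.40), miR-3152-5p (0.82 ± 0.38), miR-4467 (0.81 ± 0.33), miR-5699 (0.80 ± 0.40), miR-340-3p (0.78 ± 0.37) and miR-2355-3p (0.77 ± 0.34). None of these passed the adjusted limma test in the fit fixed beforehand. The signs are those of normalised values. Before normalisation, HT29 signals were lower in knockdown for miR-371b-5p (895.5, against 969.5 in control), miR-4467 (1841.5 and 2110.5) and miR-4787-5p (3571 and 3892). The same held in Lovo for miR-660-3p (2565 and 2769) and miR-5699 (450 and 461). For the other miRNAs named as higher, the signal was higher in knockdown in every line. In Lovo, the differences of miR-20a-5p (-0.13), let-7a-5p (-0.25), miR-23b-3p (-0.37) and miR-29b-3p (-0.30) were smaller than their SE over spots. Their sign there is uncertain, while miR-20a-5p lay at -2.30 in SW620 and miR-29b-3p at -1.45 in HT29. Also uneven were miR-371b-5p (1.81 in Lovo, 0.27 in HT29), miR-4268 (1.48 in Lovo, 0.44 in SW620) and miR-5699 (1.48 in SW620, 0.18 in Lovo). Among probes detected on all 3 control arrays and no knockdown array, miR-27a-3p was at least 2.15-fold higher in control (adjusted p from limma 0.175), miR-3146 at least 1.93-fold, miR-27b-3p at least 1.88-fold, miR-181a-5p at least 1.86-fold and miR-145-5p at least 1.69-fold. In the opposite direction miR-4653-3p was at least 1.33-fold and miR-892a at least 1.22-fold higher in knockdown.

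In Lovo the 3 highest differences among miRNAs detected on both arrays were those of miR-141-3p, miR-192-5p and miR-200c-3p. The difference was 4.02 ± 0.22 (log2, SE over spots) for miR-141-3p and 2.57 ± 0.14 for miR-200c-3p, both of the miR-200 family that holds the epithelial state by repressing ZEB1 and ZEB2, and 3.05 ± 0.19 for miR-192-5p, abundant in gut epithelium. Signals of miR-141-3p were 4531 in knockdown and 245.5 in control. Other members of the same fixed lists lay at 0.99 (miR-200a-3p), -0.16 (miR-200b-3p) and -0.24 (miR-375), and miR-429 and miR-194-5p, detected on the knockdown array only, were at least 1.89-fold and 2.38-fold higher there. The other leading probes were miR-5590-5p (2.24), miR-4708-3p (2.01), miR-485-3p (1.97), miR-3960 (1.83) and miR-371b-5p (1.81). The lowest were miR-125b-5p (-3.89 ± 0.99), miR-196b-3p (-2.22), miR-199a-5p (-2.19), miR-140-3p (-1.96), miR-193a-3p (-1.94), let-7e-5p (-1.73), miR-4639-3p (-1.69) and miR-4419b (-1.49). Not detected on the knockdown array, let-7c was at least 8.28-fold higher in control, with signals of 24.5 and 1315. Of 408 miRNAs detected on both arrays, 51 differed at least 2-fold, 25 higher and 26 lower (17 and 44 without normalisation between arrays); there is no replicate check. The knockdown array also had the lowest mean correlation with the other 5 arrays (0.633, against 0.745 to 0.812 for the others).

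Among miRNAs detected on both SW620 arrays, miR-4711-3p was the extreme, with signals of 6403 in knockdown and 54 in control (5.30 ± 0.15). Next came miR-3960 (2.76 ± 1.00), miR-3121-5p (1.87), miR-4800-3p (1.70), miR-4329 (1.50), miR-1321 (1.48), miR-5699 (1.48) and miR-5000-5p (1.46). Lower were miR-20a-5p of the proliferation-linked miR-17-92 cluster (-2.30 ± 0.78), miR-199a-5p (-1.96 ± 0.14), let-7c (-1.90 ± 0.40), let-7a-5p (-1.81 ± 0.14), miR-33a-5p (-1.63), miR-130a-3p (-1.52), miR-3651 (-1.52) and miR-140-3p (-1.52). At least 2-fold differences were counted for 53 of 368 miRNAs, 23 higher and 30 lower, again without a replicate check. The split was 15 and 36 with median scaling and turned to 44 and 16 without normalisation.

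In HT29 the lowest differences among miRNAs detected on both arrays were those of miR-29a-3p, a regulator of collagen genes (-2.74 ± 0.29), miR-142-3p, typical of blood cells (-2.15 ± 0.52), miR-193a-3p (-2.14 ± 0.25), miR-125b-5p (-2.06 ± 1.17), miR-191-5p (-1.92 ± 0.11), miR-130a-3p (-1.78), miR-140-3p (-1.77) and miR-4800-3p (-1.76). Among those not detected on the knockdown array, miR-22-3p was at least 13.6-fold higher in control (signals of 38.5 and 5047), miR-16-5p at least 7.65-fold and miR-15a-5p at least 5.64-fold. Higher were miR-4711-3p (1.70 ± 0.26), miR-335-3p (1.39), miR-1915-5p (1.36), miR-3667-5p (1.34), miR-4639-3p (1.33), miR-3152-5p (1.19), miR-30e-3p (1.17) and miR-660-3p (1.17). Of the lower miRNAs, miR-29a-3p (60.5) and miR-191-5p (79) had knockdown signals not far above the cutoff of 50. The sizes of their differences therefore depend on values near background. Of 318 miRNAs, 38 differed at least 2-fold, 16 higher and 22 lower, a split of 7 and 31 with median scaling, 8 and 31 with cyclic loess and 1 and 50 without normalisation. Plain background subtraction gave 177 in Lovo (97 higher, 80 lower), 164 in SW620 (95 and 69) and 115 in HT29 (67 and 48). At a 1.5-fold threshold the HT29 split was 71 higher and 50 lower.

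Several well-known families were lower in knockdown as lists. With camera's preset correlation 8 of 14 lists were called, all lower, and with an estimated correlation 0, the smallest adjusted p then being 0.322. The directional test of fry called 0, with a smallest adjusted p of 0.0731. In the simulations a let-7 shift of log2 1 was called in 0% with the estimated correlation and 25% with fry. Those shares come from independent noise and the let-7 list only, so how often a shift of the real lists would be called is unknown. These 0 calls alone cannot decide whether the lists shifted. The mixed test of fry, which ignores direction, gave adjusted p of 0.0196 for the list raised by TGF-β and for muscle, liver and brain markers. It gave 0.0477 for the let-7 and miR-30 families. The let-7 family, which restrains RAS and MYC, had a median log2 difference of -0.99, and 7 of 7 tested members had a mean below 0 (camera adjusted p = 0.00012; adjusted p = 0.322 with an estimated correlation). Examples detected on all 6 arrays are let-7a-5p (-1.10) and let-7b-5p (-0.82). The list of miRNAs described as raised by TGF-β had a median of -0.78 with 9 of 9 below 0 (adjusted p = 0.00012; 0.322 with an estimated correlation), among them miR-199a-5p (-1.60) and miR-24-3p (-0.78), detected on all 6 arrays. Of its members 0 passed over all miRNAs tested, and 4 passed adjusted over the list alone. The miR-17-92 cluster and its paralogues (median -0.65, adjusted p = 0.000528) and the miR-30 family (-0.91, adjusted p = 0.000528) were called as well, each at an adjusted p of 0.343 with an estimated correlation. Within the miR-30 family miR-30a-5p stood at -1.72 ± 0.29, detected on 4 of 6 arrays. With undetected values at their bounds, the medians of the 8 called lists lay between -0.99 (let-7 family) and -0.53 (fibroblast and smooth muscle markers).

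Medians of the 4 other called lists were -0.77 for the miR-15/16 family (adjusted p = 0.00792), -0.65 for miRNAs described as raised in colorectal tumours (adjusted p = 0.00897), -0.66 for fibroblast and smooth muscle markers (adjusted p = 0.00897) and -0.85 for the miR-29 family (adjusted p = 0.0307). With an estimated correlation these p-values were 0.343, 0.343, 0.343 and 0.365. That correlation was estimated at -0.02 for the let-7 family and -0.10 for the list raised by TGF-β, but at 0.17 for the miR-17-92 list, 0.27 for the miR-15/16 family, 0.32 for the fibroblast list, 0.45 for the miR-30 family and 0.90 for the miR-29 family, above the preset 0.01. The miR-15/16 family lay lowest in HT29, where 0 of its 7 members were detected on the knockdown array: with undetected values at their bounds its median was -2.49 there, -0.28 in Lovo and -0.16 in SW620. Its call was lost without the HT29 pair, as were those of the miR-17-92 and miR-29 lists. In HT29 small nucleolar RNA probes were lower in knockdown too, 10 of 12 detected on at least 1 array, with a median of -0.97 (0.94 with spike control scaling). The fibroblast list lost its call without the Lovo pair and the list raised in tumours without the SW620 pair. Lists not called were the miR-200 family (median 0.60), blood cell markers (-0.67), the imprinted cluster on chromosome arm 14q (0.24), the placental cluster on chromosome 19 (-0.08), muscle, liver and brain markers (-0.24) and miRNAs described as lowered in colorectal tumours. The last had a median of 0.05 and a mean of -0.44, which differ in sign. The gut epithelial list and the miR-34 family had 2 tested members each and were not tested.

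**Figure D2:**
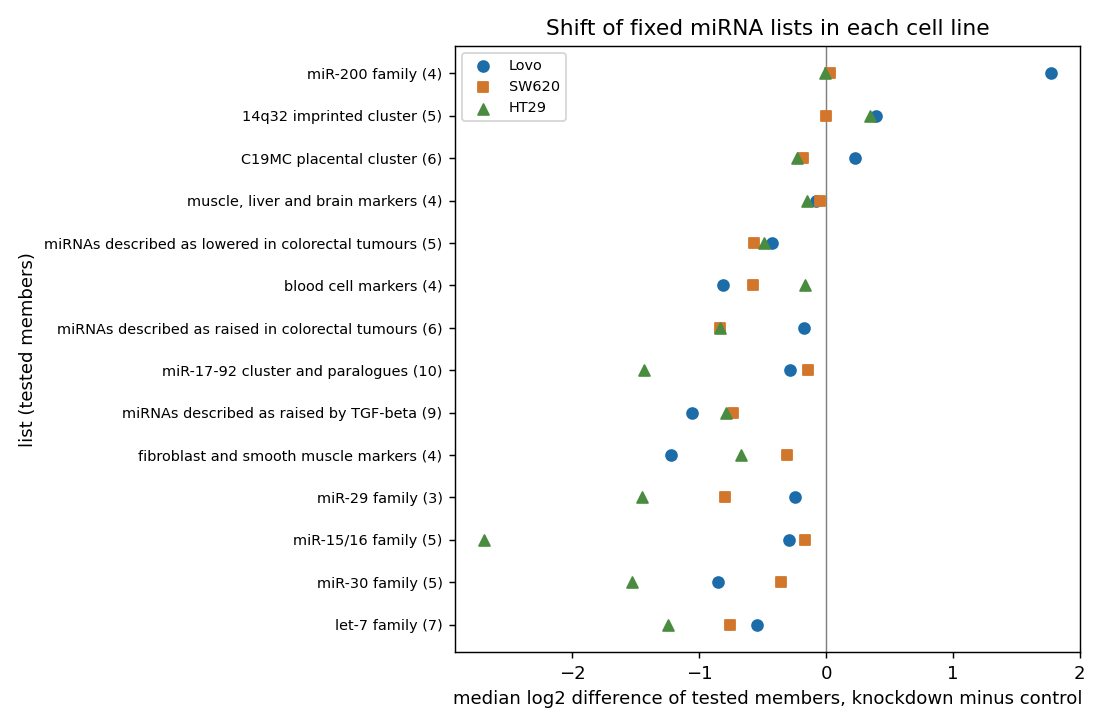
Median log2 difference (knockdown minus control, x axis) of the tested members of each list (y axis, number of members in brackets), 1 symbol per cell line. The let-7 family lies below 0 in all 3 lines, and the miR-200 family lies at 1.78 in Lovo and near 0 in SW620 (0.03) and HT29 (-0.01).

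The direction of the differences was compared between lines. Of 256 miRNAs detected on all arrays, 102 (39.8%) had the same sign in all 3 lines, 62 higher and 40 lower. The exact binomial 95% interval was 33.8% to 46.1%, which treats miRNAs as independent. Independent signs give 25% only where higher and lower are equally frequent in each line. Median differences of miRNAs detected on both arrays were 0.09 in Lovo, 0.02 in SW620 and 0.15 in HT29, so 25% may be too low a reference. Across miRNAs, which are not independent replicates, Pearson's r of the differences was 0.18 for Lovo and SW620, 0.16 for Lovo and HT29, and 0.36 for SW620 and HT29. Without normalisation between arrays the share was 29.3%.

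Between the lines the lowest F-test p-values belonged to miR-5000-3p and miR-5690, with log2 differences of 2.03 ± 0.39 and 1.63 ± 0.32 in Lovo against the mean of the other lines. Among list members, chosen after their values were seen, miR-141-3p and miR-192-5p were detected on both Lovo arrays and on no SW620 or HT29 array, and were at least 8.55-fold and 6.12-fold higher in Lovo. The Lovo difference was 1.65 ± 0.54 for miR-200c-3p, detected on 1 of those 4 arrays, -2.35 ± 0.51 for miR-142-3p and -1.48 ± 0.42 for miR-214-3p. Neither miR-142-3p nor miR-214-3p was detected on the Lovo knockdown array (signals of -31.5 and 9), so their differences rest partly on values near background. None passed: limma's F-test called 0 of 570 miRNAs, with 32 at an unadjusted p under 0.05 and a smallest adjusted p of 0.485. Without the Lovo knockdown array the 2 bounds were 2.12-fold and 2.13-fold and the 3 differences 0.33 ± 0.32, -1.90 ± 0.76 and -0.82 ± 0.36, with 7 miRNAs at an unadjusted p and a smallest adjusted p of 0.996 from limma. Without the Lovo control array the bounds of miR-141-3p and miR-192-5p were 34.5-fold and 17.6-fold, and the difference of miR-200c-3p was 2.97. Median scaling called 15, and leaving out 1 SW620 or HT29 array 8 to 24. All 5 miR-200 family members were detected on the Lovo knockdown array, 4 on the Lovo control array, 1 on the SW620 control array and 0 on the remaining arrays. Signals of miR-142-3p were 1097.5 and 1194.5 on the SW620 knockdown and control arrays and 217 and 2645 on those of HT29; whether these RNAs came from the named lines was not tested, which bears on every difference between lines. Arrays did not group by line, with a mean correlation of 0.740 within lines, 0.782 within shRNA groups and 0.724 for pairs sharing neither.

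**Figure D3:**
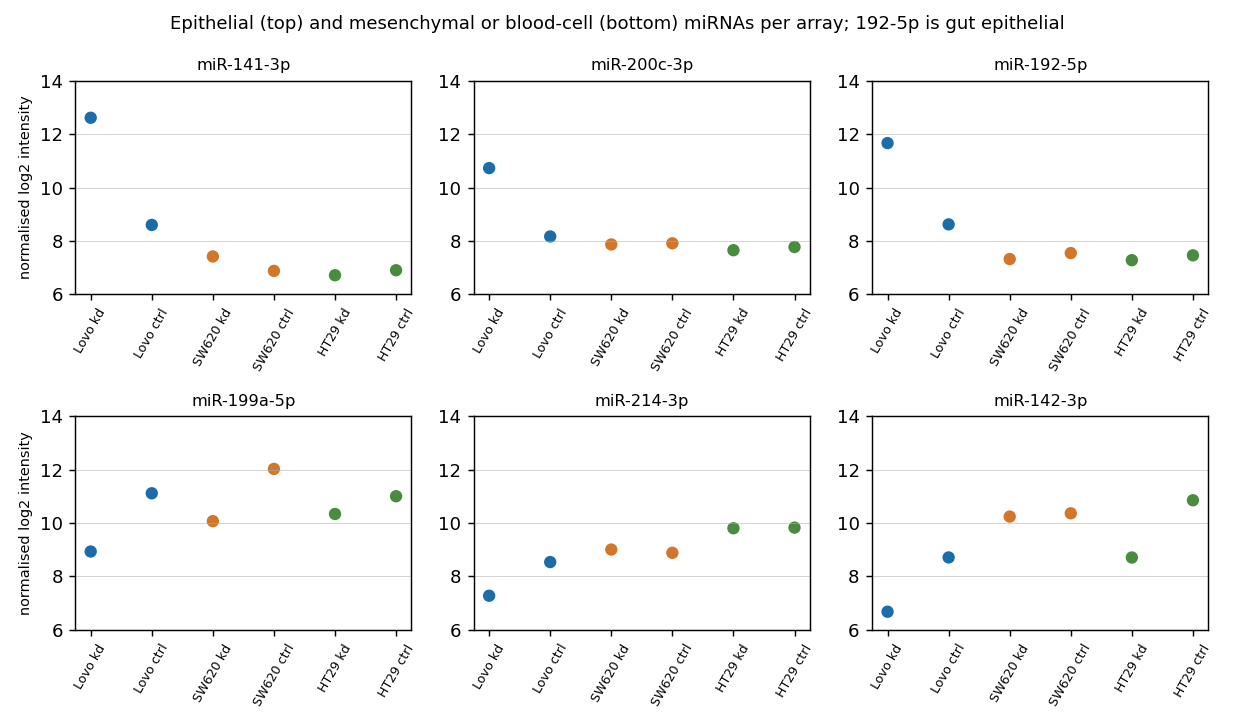
Normalised log2 intensity (y axis) of 3 epithelial miRNAs (top) and 3 miRNAs of mesenchymal or blood cells (bottom) on each of the 6 arrays (x axis; kd, knockdown; ctrl, control). On the Lovo knockdown array miR-141-3p lies at 12.62 and miR-142-3p at 6.67; on the HT29 control array they lie at 6.90 and 10.85.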

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

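The patterns tested below were found in the results. The tests of spike control probes, of scaling and of exchanged arrays were chosen after the results were seen. For those of other early-numbered miRNAs and of background, only the predictions were written before the tests were run.

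For 7 miRNAs the 2 arrays of a line differed at least 2-fold one way and those of another line at least 2-fold the other way. With 1 array per condition the differences between lines were not tested. Log2 differences were 1.83 in Lovo and 2.76 in SW620 but -1.20 in HT29 for miR-3960, 1.70 in SW620 and -1.76 in HT29 for miR-4800-3p, and -1.69 in Lovo and 1.33 in HT29 for miR-4639-3p. They were -1.07 in Lovo and 1.50 in SW620 for miR-4329, -1.26 and 1.46 in the same lines for miR-5000-5p, -1.42 in Lovo and 1.00 in HT29 for miR-1827, and -1.02 in SW620 and 1.01 in HT29 for miR-3157-3p. Outside the human probes, 24 of 146 viral miRNA probes were detected on all 6 arrays, a share no lower than the 256 of 1891 human probes. Detection at the cutoff of 50 may therefore include signal that is not specific to the named miRNA, which was not tested.

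The first pattern is the lower level of fixed families, such as let-7 and miR-30, on the knockdown arrays. Poorer labelling or hybridisation would also lower the spike control probes. In SW620 their median log2 difference was 0.74 ± 0.28 (bootstrap SE over 16 probes, 3 of them lower), the opposite direction, while it was -0.79 in Lovo and -1.39 in HT29 (small nucleolar RNAs, by contrast, had a median of 0.44 in Lovo and of -0.97 in HT29, or 0.94 there with spike control scaling), so in Lovo and HT29 the explanation cannot be told apart from a change in the cells. The choice of scaling was argued against only for means over the 3 lines. Under 4 other scalings all 32 mean shifts of the 8 lists stayed below 0, the highest being -0.25. Single lines were not tested under these scalings. In HT29 the median of the list members was -1.71 without normalisation between arrays. There spike control scaling moved the small nucleolar RNA median from -1.38 to 0.94, so for HT29 alone scaling is not argued against. This move exceeds the median spike difference of -1.39, because the scaling used each array's median over the spike probes and not per-probe differences. Scaling by per-probe differences was not run, so the turn to 0.94 may rest on that choice. A common shift of all miRNAs with early registry numbers is argued against weakly: list members lay below other such miRNAs by a mean of -0.71 ± 0.26 over 3 lines, but the 8 lists were picked for being low, and over all 14 lists the mean was -0.40 ± 0.18.

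Whether chance can be excluded stays open, because only 4 splits of the arrays part all 3 pairs, too few for a share under 0.05; the other splits keep both arrays of some line together. The real split called 8 lists, as did 1 of the 4, itself, and the highest other called 4. For single miRNAs the real split called 0 and the highest other 1, so that 4 of 4 splits gave as many. With the HT29 labels exchanged, as the conflicting label field might imply for 1 of its samples, 0 lists were called, with those of Lovo exchanged 2, and with those of SW620 exchanged 4. An effect of the TGFB1 shRNA remains possible and was not tested apart from these.

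The second pattern is the Lovo knockdown array, where 6 of the 10 members of the miR-200 and gut epithelial lists were brighter (miR-141-3p, miR-200c-3p, miR-192-5p, miR-200a-3p at 0.99, and at least 1.89-fold and 2.38-fold miR-429 and miR-194-5p), miR-200b-3p (-0.16) and miR-375 (-0.24) were not, and 2 were detected on no Lovo array. A swap with an SW620 or HT29 array would put miR-200 family members on one of those, yet none detected more than 1. This argues against a swap only if Lovo knockdown RNA carries the family, as Lovo control RNA did (4 of 5 detected). The identity of the RNAs was not tested. Lower background on this array is argued against only for miR-141-3p, miR-192-5p and miR-200c-3p, the highest Lovo differences. Without background correction these were 4.02, 3.11 and 2.61, and those of miR-200a-3p and miR-200b-3p were 0.88 and -0.14. The median of miR-192-5p and the 4 miR-200 family members detected on both Lovo arrays was 2.61. For miR-429 and miR-194-5p, detected on the knockdown array only, background was not tested. A swap of both Lovo arrays cannot be told apart from the labelled order with 1 array each; as labelled, the Lovo differences correlated with those of the other lines at 0.16 or more. A change in the Lovo cells may also be the cause, as may RNA of other cells on the SW620 and HT29 arrays, where miR-192-5p and nearly all of the miR-200 family were not detected while miR-142-3p reached 1097.5 to 2645 on 3 of 4; neither was tested, and the second would bear on every difference between lines.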

How the results depend on the processing

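Spike control scaling, robust eBayes and the fits without low-variance probes were chosen after seeing the data. Under the alternatives run, no difference named across lines (24 ranked, 13 bounds or list members), between lines (7) or in a single line (48 ranked, 15 others) changed sign. Neither did the mean over lines of any of the 8 called lists. Across lines only the mean was followed, so a shared sign in every line may be lost under an alternative. Differences in single lines and between lines were not rerun with spike control scaling. That scaling moved the small nucleolar RNA median in HT29 from -0.97 to 0.94, so single-line signs may change under it. The bounds of miR-429 and miR-194-5p in Lovo and those between lines were not rerun under the alternatives. Of 158 values between lines, 60 passed the threshold. Of the lists not called, the mean of the placental cluster moved to 0.52 with spike control scaling, that of muscle, liver and brain markers to 0.33 and that of miRNAs lowered in tumours to 0.06; the placental mean also lay just above 0 in 3 other settings. For the 24 miRNAs named across lines, 472 values stayed on the same side of the threshold and 31 passed it. For the 14 lists, 246 of 278 list tests gave the same call, 10 gained and 22 lost one, and of 528 values named per line 438 stayed within 2 SE over spots.

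The count of 0 miRNAs changed across lines became 32 with median scaling, 5 with cyclic loess, 13 with the authors' value table, 61 at an unadjusted p, 2 without the probe of zero variance, 5 without the 3 of lowest variance and 6 with robust eBayes. Leaving out 1 pair gave 0 to 25. Fits with more calls had larger prior degrees of freedom, infinite with median scaling and without the SW620 or HT29 pair, where each variance is taken from the trend over all probes, and leaving out a pair leaves 1 residual degree of freedom; such calls say little about single miRNAs. With spike control scaling, infinite prior degrees of freedom gave 0 calls, and 1 miRNA at an unadjusted p in place of 61. The fit with no replicate block (pairing by line) gave 0.

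For differences between lines 0 became 15 with median scaling, 1 with cyclic loess, 3 with the value table, 4 without the 3 probes of lowest variance and 2 with robust eBayes, and 0 to 24 on leaving out a pair or an array; the cause was not tested. The 8 called lists became 4 among miRNAs detected on all 6 arrays, where only 4 lists had enough members to be tested. All 4 kept their call. The 8 became 0 with an estimated correlation and 0 with the directional test of fry.

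Of the miRNAs counted in Lovo, SW620 and HT29, 12.5%, 14.4% and 11.9% differed at least 2-fold. The shares were 43.4%, 44.6% and 36.2% with plain subtraction and 34.6%, 39.7% and 31.8% with the value table, the cause of which was not tested; an offset of 16 alone gave 15.2%, 17.1% and 15.1%. A 1.5-fold threshold gave 33.8%, 37.5% and 38.1%, and no filter, with all 1891 probes counted, 5.13% in Lovo, 3.86% in SW620 and 6.35% in HT29. Without normalisation the median difference of tested miRNAs was -0.22 in Lovo, 0.13 in SW620 and -0.31 in HT29, and with median scaling -0.20 in SW620; the cause of the changed splits of higher and lower was not tested. The share with 1 sign in all lines was 29.3% without normalisation, the cause of which was not tested, and 28.7% with no filter, where most probes are near background. Signal over background limits these counts: 1321 of the human probes were detected on fewer than 2 arrays.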

Other observations

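Small nucleolar RNAs, many of which guide the modification of ribosomal RNA, differed in direction between the lines. Of those detected on at least 1 array of a line, 12 of 15 were higher in knockdown in Lovo, 6 of 14 in SW620 and 2 of 12 in HT29, with median log2 differences of 0.44, -0.08 and -0.97. The median turned to 0.94 in HT29 with spike control scaling and to 0.14 in SW620 without normalisation between arrays. SNORD3@ had a log2 difference of 2.90 in Lovo, -0.15 in SW620 and -2.73 in HT29, SNORD68 lay at 0.78, 0.70 and -2.44, and SNORD4A lay at -0.62, -1.94 and -1.10. The U6 probe named RNU6-1_RNU6-2, of a type often used as a reference, lay at -0.80, 0.86 and -1.33. A dimmer U6 probe, RNU6-1, was not detected on the Lovo knockdown array (9.5, against 149.5 in control) and lay at -0.27 in SW620 and -0.24 in HT29. These are single arrays with no test.

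Among probes without a name, 578 were detected on at least 2 arrays, and limma called 0 of them, with 57 at an unadjusted p under 0.05 (12 higher and 45 lower in knockdown). The brightest viral probe, hsv1-miR-H4-3p, had signals of 1694.5 and 4029 on the Lovo knockdown and control arrays.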
